A study of Mus musculus with 2 samples.

How the data were processed

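Enrichment peaks along the genome were compared between 2 libraries of E14 mouse embryonic stem cells, a widely used line of pluripotent cells. One culture carried a short hairpin RNA against GFP, the control, and the other a hairpin against Dnmt3L, a catalytically inactive partner of the de novo DNA methyltransferases. Each group held 1 library, so no value has a replicate error, no p-value was computed, and every difference below is a difference between these libraries.

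The sources disagree on the modification that was captured. Per the labels, the samples are named as MeDIP, and the series design speaks of 5-methylcytosine. Per the labels' protocols, sonicated genomic DNA was instead enriched by a glucosylation-based method with the Hydroxymethyl Collector kit, which captures 5-hydroxymethylcytosine. The peaks are therefore called enrichment peaks here, without naming the modification.

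The deposited files were 1 peak list per library, with a position, a peak name and a score for each peak. The score in column 5 is the value the authors' peak caller gave to each peak. Its lowest values, 50.01 in shGFP and 50 in shDnmt3L, are what a p of 1e-05 gives when −log10 of p is multiplied by 10, as MACS of this generation writes it. This reading rests on the values. The submitters' processing notes list CASAVA 1.8, Bowtie 0.12.7, MACS 1.4.1 and the build mm9. They give no roles. The use of an input control, the treatment of duplicate or repeat reads, and the read depth are not given in the sources used here. Read depth is unknown, and the number and width of called peaks can move with it, with fragment length and with the control. Scores rank or describe peaks within their own list. The one exception is a minimum score of 100 set on the lists, and since the depths are unknown, the same score need not stand for the same enrichment in both.

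Coordinates are those of the files with the first base counted as 1, on mm9 per the submitters' processing notes. The only reference at hand was a gene table of another build, GRCm38, and on 10 chromosomes a peak ended beyond the last gene of that table. No coordinates were converted, and no gene, promoter or CpG island was assigned to a peak. The planned counts for promoters, gene bodies, CpG content and gene lists were not made for this reason. The level of the targeted gene was not analysed here.

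Peaks were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A peak was shared when it overlapped a peak of the other list by at least 1 bp. The overlap expected by chance was the mean of 100 draws in which the other list was shifted circularly within each chromosome by a random distance. Shares carry Wilson 95% intervals, peak numbers exact Poisson intervals, and ratios between the libraries exact conditional binomial intervals. These intervals cover counting error only and treat peaks as independent, which neighbouring peaks and lists with common peaks are not. Chromosomes and windows were compared by their share of each list, to allow for the different list lengths. Chromosome length was taken as the end of the last peak in either list. Windows of 1 Mb were used where the lists together held at least 20 peak midpoints.

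Regions named in the text followed a rule fixed before the data were examined. It took the 5 windows with the highest and the 5 with the lowest ratio of shares. In each library it also took the 5 peaks of highest score and the 5 of highest score with no overlap in the other list. The fixed rule gave no order for peaks tied in score, and these were ordered by width. The class of peaks at least 10 kb wide, and the regions named from it, were chosen after the values were seen. The alternatives tried were a minimum score of 100, lists of equal length, peaks within 500 bp merged, other overlap rules, covered length in place of peak number, windows of 500 kb and, added later, other minimum widths and lists without chromosome 8.

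The overlap code was tested on simulated data for the comparison of shDnmt3L with shGFP. In a simulated list that kept 79.9% of the 55292 shGFP peaks, 80.0% were found again. In 200 simulated windows with a 2-fold higher rate, 71.5% had an interval above 1, and 3.78% of 1270 unchanged windows had an interval that excluded 1. The simulated window counts were drawn independently for each list, whereas the real lists share most of their peaks. These window rates therefore need not hold for the real lists.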

Results

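Enrichment peaks were compared between E14 embryonic stem cells carrying a control hairpin (shGFP, 1 library) and a hairpin against Dnmt3L (shDnmt3L, 1 library), to ask where the modification captured by the assay changed when Dnmt3L was targeted. The shGFP list held 55292 peaks (95% Poisson interval 54832 to 55755) and the shDnmt3L list 45579 (45162 to 45999). Neither library had a replicate, so the differences below have no replicate check.

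The shDnmt3L library had fewer but wider peaks than the control library. Its list was 9713 peaks shorter, or 17.6% of the shGFP list, yet its peaks covered 124 Mb against 118 Mb, which was 5.23% more. The median peak was 2376 bp wide in shDnmt3L and 1998 bp in shGFP. Among 37952 pairs of peaks that overlapped one to one, 81.7% were wider in shDnmt3L, and the median difference was 145 bp (quartiles 32 and 402 bp). The shDnmt3L start lay exactly 32 bp outside the shGFP start in 20.7% of these pairs and on the same base in 19.02%. More than 64 bp of extra width, 32 bp at each end, was found in 62.1% of the pairs. Below 2 kb, shGFP had 27694 peaks and shDnmt3L 10427. Between 4 and 6 kb the order was the opposite, with 1763 peaks in shGFP and 3709 in shDnmt3L. The outcome of this comparison depended on the measure, since peak number was lower and covered length higher in shDnmt3L.

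Long stretches of enrichment were more numerous in the shDnmt3L library, and part of them had no called peak in the control library. Peaks of 10 kb or more numbered 244 in shDnmt3L (95% Poisson interval 214 to 277) and 29 in shGFP (19.4 to 41.6), a ratio of 8.41 (exact 95% interval 5.71 to 12.8). All 29 broad shGFP peaks overlapped a shDnmt3L peak, with a median of 99.8% of their length under shDnmt3L peaks. Of the 244 broad shDnmt3L peaks, 104 (42.6%, Wilson 95% interval 36.6 to 48.9%) overlapped no shGFP peak at all. A further 72 lay over 1 shGFP peak and 68 over 2 or more. When the minimum width in shDnmt3L was scaled up by the ratio of the median widths, to 11.9 kb, 132 broad peaks were left, 60 of them with no shGFP peak. With peaks within 500 bp merged the numbers were 97 in shGFP and 400 in shDnmt3L, 115 of the latter with no shGFP peak, at 5 kb or more they were 742 and 2363, with 561 unshared, and without chromosome 8 they were 17 and 186. The ratio of broad peak numbers was below 5.71 with the scaled width, with merging and at 5 kb, and above 8.41 without chromosome 8. Its interval thus covers counting error at 10 kb only, not the choice of setting.

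**Figure D1:**
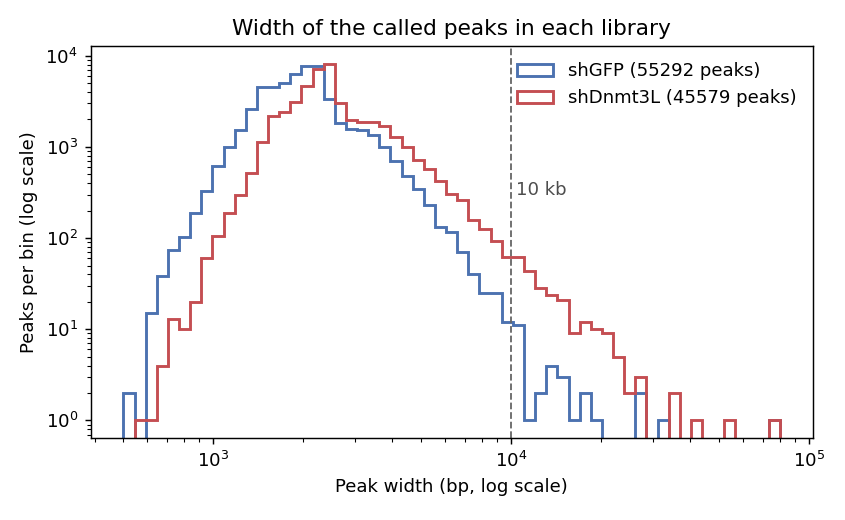
Number of peaks (vertical axis, log scale) by peak width in bp (horizontal axis, log scale) in the shGFP and shDnmt3L libraries, with 10 kb marked by the dashed line. To the right of that line lie 29 shGFP peaks and 244 shDnmt3L peaks.

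Of the 21 shDnmt3L peaks with a score of 3100 or more, 15 were broad, as were 10 of the 17 such peaks in shGFP. Because 19 shDnmt3L peaks tied at 3100 and ties were ordered by width, the named peaks from rank 3 on are the widest of that tie. Another 16 peaks had this value in shGFP. So many equal values may mark a ceiling of the score, so the order of peaks at 3100 or above need not follow enrichment. On chromosome 6, the interval from 52149804 to 52205525 was 1 continuous shDnmt3L peak of 55.7 kb with a score of 3100, and the single shGFP peak under it covered 3.48% of its length. Peaks touching the surrounding 160 kb numbered 10 in shDnmt3L, with a summed width of 120 kb, and 2 in shGFP, with 3.80 kb. Full widths were summed, and a 20.3 kb shDnmt3L peak from 52254316 to 52274641 ran past the end of this stretch at 52257664. On chromosome 11, the interval from 96129072 to 96169366 was a shDnmt3L peak of 40.3 kb, of which 4.79% lay under a shGFP peak. The top-scoring peak of the shDnmt3L list, from 151831905 to 151835374 on chromosome 4, was 3470 bp wide with a score of 3204, and 95.2% of it lay under a shGFP peak. The peak of second rank, from 123592084 to 123615657 on chromosome 8, scored 3153 and overlapped 4 shGFP peaks that covered 51.6% of it.

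The 5 strongest shDnmt3L peaks with no shGFP overlap were all over 20 kb wide. The first lay on chromosome 11 from 118894950 to 118922607, was 27.7 kb wide and had a score of 2649. Its nearest shGFP peak was 2143 bp away. The others were a 26.2 kb peak on chromosome 19 from 44812076 to 44838311 with a score of 2008, and a 21833 bp peak on chromosome 2 from 71363503 to 71385335 with a score of 1852. A 23.2 kb peak on chromosome 9 from 74693096 to 74716325 had a score of 1840.5, and a 23.7 kb peak on chromosome 4 from 139371341 to 139395061 had a score of 1765. The nearest shGFP peaks to these 4 were 3542, 18555, 26367 and 5052 bp away, in the same order.

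**Figure D2:**
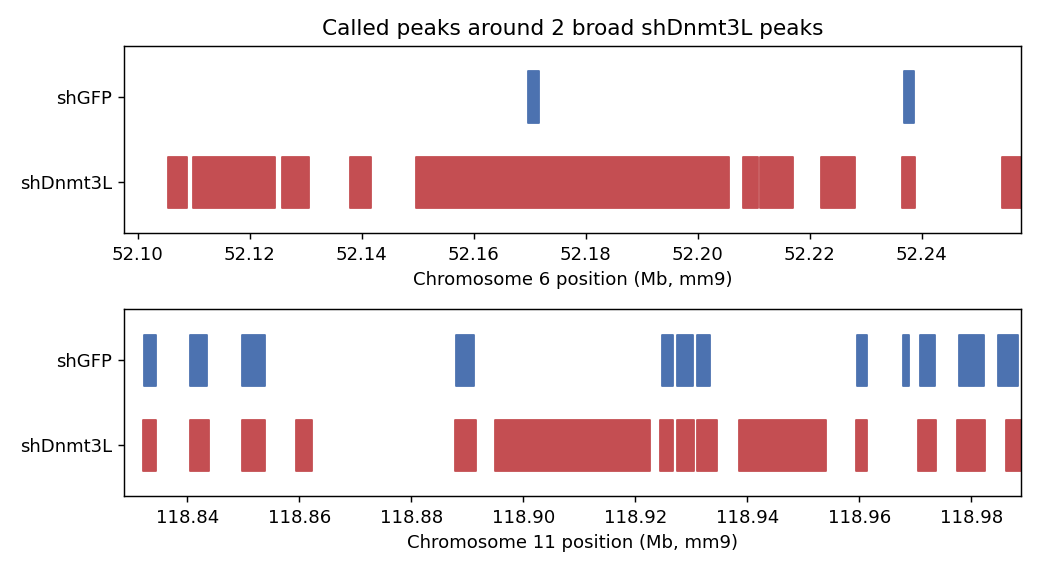
Called peaks of both libraries along 160 kb of chromosome 6 (upper panel) and of chromosome 11 (lower panel), with mm9 positions in Mb and each box spanning 1 peak, clipped at the panel's edge. The 55.7 kb shDnmt3L peak on chromosome 6 has 1 narrow shGFP peak above it, and the 27.7 kb peak on chromosome 11 has none, while flanking peaks on chromosome 11 appear in both libraries.

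No shGFP peak of 10 kb or more lacked a shDnmt3L partner. The strongest shGFP peaks with no shDnmt3L overlap were a 642 bp peak on chromosome 1 from 50317372 to 50318013 and a 542 bp peak on chromosome 14 from 6042853 to 6043394, both with a score of 279. They were followed by a 4721 bp peak on chromosome 5 from 37516125 to 37520845 with a score of 201, and by an 830 bp peak on chromosome 4 from 81111454 to 81112283 that also scored 201. The fifth was a 3409 bp peak on chromosome 4 from 150866713 to 150870121 with a score of 199.65. The nearest shDnmt3L peaks to these 5 were 633628, 1117513, 24458, 668086 and 3059 bp away, in the same order. The narrowest peak of the whole shGFP list was 510 bp wide. The 5 highest-scoring shGFP peaks overall lay on chromosomes 10, 11, X, Y and 17, and each had at least 97.1% of its length under shDnmt3L peaks. All but the first were the widest of 16 peaks tied at a score of 3100. The widest of the 5, 74190 bp on chromosome 11 from 3026531 to 3100720, matched the widest shDnmt3L peak of 74393 bp.

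Most peaks were found in both libraries. Of the shGFP peaks, 74.5% (Wilson 95% interval 74.1 to 74.8%) overlapped a shDnmt3L peak, against 9.52% (SD 0.579 over 100 draws) when the shDnmt3L list was shifted at random. Of the shDnmt3L peaks, 87.4% (87.1 to 87.7%) overlapped a shGFP peak, against 11.2% (SD 0.649) by chance. With lists of equal length these shares were 84.3% and 82.2%, so the order of the libraries reversed. The 14107 shGFP peaks without a partner were narrow and low in score, with a median width of 1605 bp against 2111 bp for shared peaks and a median score of 60.6 against 122. The 5724 shDnmt3L peaks without a partner had a median width of 2474 bp, against 2366 bp for shared peaks, and a median score of 74.9 against 103.

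The relation of sharing to score differed between the lists. In shGFP, the share of peaks with a shDnmt3L partner went from 24.97% in the lowest decile of scores to 100% of 5530 peaks in the highest decile (lower bound 99.9%). In shDnmt3L it went from 73.1% in the lowest decile to 92.1% in the seventh, and was 90.6% in the highest (89.8 to 91.4%). At scores of 100 or more, 585 of 26516 shGFP peaks had no partner, with a median width of 1825 bp. In shDnmt3L, 1940 of 22565 such peaks had none, with a median width of 4021 bp. The same score need not stand for the same enrichment in the 2 libraries.

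**Figure D3:**
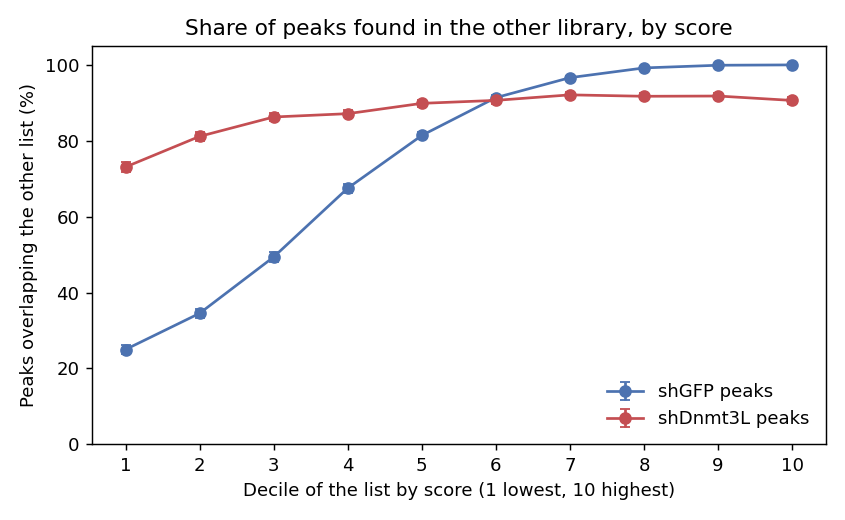
Share of each library's peaks that overlap a peak of the other library (vertical axis, percent) by decile of the list in order of score (horizontal axis), with Wilson 95% intervals. The shGFP curve reaches 100% in the highest decile, whereas the shDnmt3L curve stays at 90.6%.

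By chromosome, both lists had the same outline, with chromosome 8 densest and the X chromosome nearly empty. Chromosome 8 held 5621 shGFP peaks, or 42.8 per Mb, and 4977 shDnmt3L peaks, or 37.9 per Mb. The next densest autosome had 31.2 peaks per Mb in shGFP and 26.5 in shDnmt3L. The X chromosome held 202 shGFP peaks, or 1.21 per Mb, and 151 shDnmt3L peaks, or 0.907 per Mb, against autosomal medians of 21.1 and 17.7 per Mb. The share of peaks on chromosome 8 was 10.2% in shGFP and 10.9% in shDnmt3L, a ratio of 1.07 (exact 95% interval 1.03 to 1.12). It was the only 1 of 22 chromosomes whose interval excluded 1. With lists of equal length the log2 ratio on chromosome 8 was 0.041 (−0.016 to 0.099), so that call was not kept. With both lists at scores of 100 or more it was 0.106 (0.034 to 0.178), and the call was kept. The call thus depended on the setting. For the X chromosome the ratio was 0.907 (0.730 to 1.13), and a difference was not detectable from these peak numbers. The other 18 autosomes had ratios between 0.957 and 1.03.

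**Figure D4:**
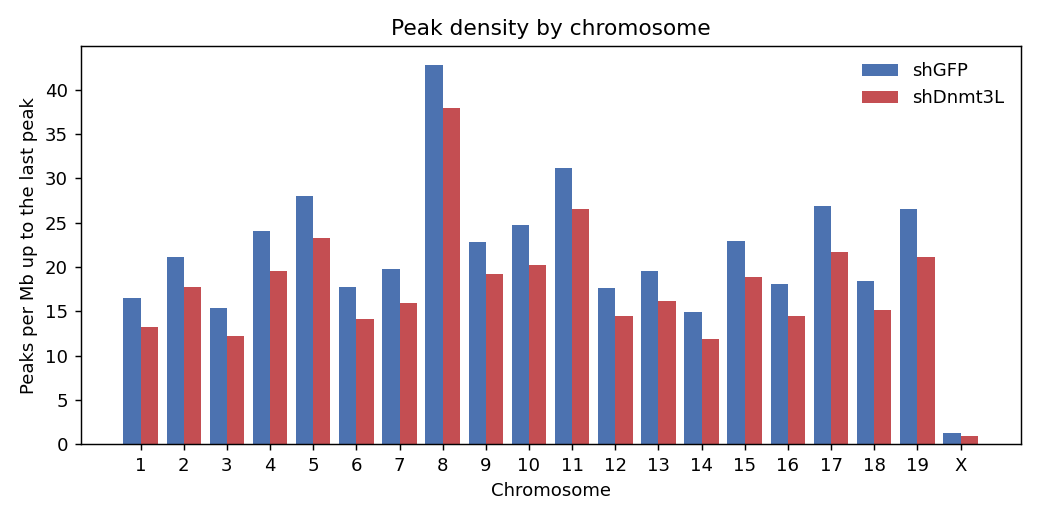
Peaks per Mb (vertical axis) on each autosome and the X chromosome (horizontal axis) in the shGFP and shDnmt3L libraries, with length taken up to the last peak. Chromosome 8 stands highest in both libraries, at 42.8 and 37.9 peaks per Mb, and X lowest, at 1.21 and 0.907.

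At the scale of 1 Mb, 1 of 1390 windows had a ratio of shares whose interval excluded 1. This window, on chromosome 18 from 37000001 to 38000000, held 21 peaks in shGFP and 47 in shDnmt3L, a ratio of 2.72 (exact 95% interval 1.59 to 4.78). Of its shDnmt3L peaks, 28 had no shGFP partner, and the covered length was 153 kb against 45.3 kb. None of these peaks reached 10 kb. The window of second rank, on chromosome 2 from 74000001 to 75000000, held 18 and 27 peaks, a ratio of 1.82 (0.966 to 3.51), and 4 broad peaks in shDnmt3L against 0 in shGFP, with covered lengths of 129 and 34.4 kb. The next 3 windows began at 49000001 on chromosome 14, at 77000001 on chromosome 7 and at 115000001 on chromosome 2, with ratios of 1.82, 1.62 and 1.58 and intervals that included 1.

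The 5 windows with the lowest ratios began at 41000001 on chromosome 12, 93000001 on chromosome 6, 51000001 on chromosome 1, 83000001 on chromosome 9 and 100000001 on chromosome 14. Their ratios were 0.357, 0.455, 0.485, 0.511 and 0.520. The first held 17 shGFP and 5 shDnmt3L peaks, with an interval of 0.103 to 1.01, and the intervals of the other 4 also included 1. The spread of the log2 ratio over the 1390 windows was 0.245 (SD), below the 0.434 that independent counting of the same totals gave, so the intervals were wide for lists that share most of their peaks.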

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

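Of 58 alternative values computed, 25 stayed within the range set for them, 32 moved beyond it and 1 reversed. For shares and ratios the range was the counting interval, and covered length used that of peak number. Chance overlap used the SD over draws, and counts of windows and broad peaks a factor of 1.5. Differences in median score were called the same if they kept their sign. Some outcomes were fixed by the setting, so the counts of same and moved values do not measure how stable the results are. With lists of equal length the shDnmt3L list stayed whole, and its 244 broad peaks could not change. The scaled width left the shGFP minimum at 10 kb, so the 29 broad shGFP peaks could not change. Minimum widths of 5 and 20 kb redefine the class. Of the 58 values, 19 were differences or ratios, which have a direction to lose. Those of chromosome X were not checked for reversal, though all kept their sign. The alternatives for broad peaks and those without chromosome 8, and the difference between the shared shares, were added after the data were seen. The reversal was in that difference, 13.0 percentage points higher in shDnmt3L in the full lists and −2.08 with lists of equal length. It was 10.8 with both lists at a score of 100 or more, 14.5 at 50% overlap, 12.3 within 500 bp and 13.8 without chromosome 8. With both lists limited to scores of 100 or more, the log2 ratio of peak numbers (shDnmt3L over shGFP) was −0.23 against −0.28, that of covered length 0.17 against 0.07, and the shared share was 73.3% of shGFP and 84.1% of shDnmt3L peaks. With lists of equal length, the log2 ratio of covered length was 0.28, the shared shares were 84.3% and 82.2%, and the log2 ratio of shares on chromosome 8 was 0.041 against 0.10. Asking for an overlap of 50% of both peaks gave 68.1% and 82.6%, and counting peaks within 500 bp gave 75.6% and 87.9%. Without chromosome 8, 73.4% of shGFP peaks were shared and 17 shGFP peaks were broad. Windows with an interval above 1 numbered 2 at the higher score, 2 with equal lengths and 3 at 500 kb, where 1 window had an interval below 1. At 5 kb or more, the broad peaks were 742 in shGFP and 2363 in shDnmt3L, 561 of them without a shGFP peak, and at 20 kb or more they were 4, 25 and 9. With the width scaled by the median widths, 132 shDnmt3L peaks remained broad, 60 without a shGFP peak, and with peaks within 500 bp merged there were 97 in shGFP and 400 in shDnmt3L. The cause of these shifts was not tested beyond what each setting does by construction. The alternatives for promoters, gene bodies, CpG content and gene lists were not run, since no annotation of the build was used. No paired analysis was possible because each group has 1 library. Read depth, which sets how many weak peaks can be called, is unknown.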

Other observations

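The tests on joined peaks among all broad peaks, on score cutoffs, on capture and on a gained chromosome copy were chosen after the values they use were seen; the test on joined peaks over 2 or more control peaks and that on dense stretches were set before their values were computed, on patterns already seen. The 104 broad shDnmt3L peaks with no shGFP peak were spread over 18 chromosomes and formed 92 groups when peaks within 100 kb were joined, 9 of which held 2 or more broad peaks. The largest sum of broad peak width lay on chromosome 15 from 102782689 to 102847619, where 3 broad peaks made up 53.9 kb and no shGFP peak was called. Next was chromosome 2 from 74503707 to 74593421, with 4 broad peaks of 53.8 kb in all and no shGFP peak. After it came groups beginning at 118894950 on chromosome 11 (43.1 kb), 86005924 on chromosome 17 (39.5 kb) and 42295822 on chromosome 10 (29.1 kb). The spans of these groups held 3, 4 and 1 shGFP peaks, in the same order, outside the broad peaks themselves. On chromosome 11, groups of 2 lay from 96185412 to 96217348 (29.0 kb) and from 96031666 to 96059461 (25.3 kb), on either side of the 40.3 kb peak at 96129072. On chromosome 6, broad peaks of 14.6 kb from 52109877 to 52124512 and of 20.3 kb from 52254316 to 52274641 lay within 100 kb of the 55.7 kb peak at 52149804, 1 on either side. The median score of the 104 peaks was 875, and all 104 scored above the 95th percentile of their list, 428. Score rose with width in both lists, so peaks picked for a width of 10 kb or more were likely to rank high. In shDnmt3L the median score was 67.4 below 2 kb and 1019 for all 244 broad peaks.

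Chromosome 8 held 58 of the 244 broad shDnmt3L peaks and 12 of the 29 broad shGFP peaks, but 2 of the 104 without a shGFP peak. The mitochondrial genome carried 1 peak in each library, of 6859 bp in shGFP and 6897 bp in shDnmt3L, with a score of 3100 in both. A score of exactly 3100 was given to 16 shGFP and 19 shDnmt3L peaks.

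The broad shDnmt3L peaks absent from the control list are the pattern most worth following up. Joining of called control peaks cannot apply, by definition, to the 104 broad peaks with no shGFP peak, so they are no test of it. Among all 244 broad peaks, 27.9% (Wilson 95% interval 22.6 to 33.8%) lay over 2 or more shGFP peaks. This argues against joining as the whole cause of the 244, but it restates counts already seen and is no separate test. For the 68 over 2 or more shGFP peaks, a median of 69.8% of their length (quartiles 48.0 and 90.7%) was under shGFP peaks, so joining may account for them. A score cutoff in the control list would leave the strongest shDnmt3L peaks shared, but 90.6% of their highest score decile were (interval 89.8 to 91.4%). That decile was also the widest, with a median of 4094 bp, and score rose with width. A high score therefore need not mean strong local enrichment, so this result cannot decide on a cutoff for the broad peaks. A score cutoff may account for unshared shDnmt3L peaks of lower score, since the shared share was 73.1% in the lowest decile against 90.7% in the sixth, and 3784 of the 5724 unshared peaks scored below 100. A difference in capture or background between the preparations, including GC bias, and an effect of targeting Dnmt3L cannot be told apart, since there was 1 library per group and neither an input library nor the genome sequence was used here.

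For the 14107 shGFP peaks without a shDnmt3L partner, the explanation tested was the score cutoff of the shDnmt3L list, under which the share with a partner should reach nearly all of the strongest peaks; it was 100% in the highest score decile (lower bound 99.9%). Score rose with width in this list too, with a median width of 1581 bp in the lowest decile and 2809 bp in the highest. A high score need not mean strong local enrichment here either, so this result cannot decide on a cutoff. A lower effective depth or a weaker enrichment in the shDnmt3L library may account for the shGFP peaks without a partner. Neither was measured, and neither addresses the wider peaks of the same library (median 2376 against 1998 bp) or its larger covered length (124 against 118 Mb). A modest loss of the modification at many sites would look alike in peak lists and was not tested.

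Chromosome 8 was the densest autosome in both libraries, so the hairpin does not separate it. A few dense stretches are argued against as the whole cause: without the 2 densest 10 Mb segments of every autosome, chromosome 8 still had 32.8 peaks per Mb in shGFP and 28.8 in shDnmt3L, against at most 25.2 and 21.4 on any other autosome. A gained copy of chromosome 8 in the cultures and its sequence composition stay open and cannot be told apart. Of its 13 complete segments, 84.6% in shGFP and 92.3% in shDnmt3L were above the median autosomal segment, but another autosome reached 83.3% in both libraries, and a chromosome picked for its density would show this with either explanation. Its median peak scores, 117 and 122, exceeded those of the other 18 autosomes (at most 102 and 106), and density also varied along the chromosome, with 64 to 1157 shGFP peaks per complete segment.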
